A study of Mus musculus with 12 samples.

How the data were processed

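Gene expression was measured in W9.5 cells, a mouse embryonic stem cell line, on 12 Illumina expression BeadChip arrays. The arrays fall into 4 days of a sequential differentiation (days 0, 4, 8 and 15) with 3 arrays per day. Per the labels, total RNA was amplified and labelled as biotinylated cRNA, and the cells passed through activin A, retinoic acid, and retinoic acid plus fibroblast growth factor in that order. The labels carry the same treatment text for all 12 arrays, day 0 included, and do not say on which days each agent was present. They do not say that the replicates were separate cultures, so no p-value below can be read as measuring a spread between cultures. The p-values of single genes measure only the spread between these arrays. Tests of gene lists set the members against other genes, and Fisher's exact tests and the permutation over genes take genes as their units.

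The deposited scanner table gives an intensity for each of 24613 probes on each array, not background-subtracted and not normalized, and beside it a detection p-value. The authors' value table holds log2 intensities, which increase with the scanner intensity within every array (rank correlation 1), equal its plain log2 on day 15 replicate 2, and have a median between 6.27 and 6.30 on every array; the normalization method is not given in the sources used here. The table of probes and genes that came with the files names 1 gene for 20984 probes, several for 1 probe and none for 3628. Of the 15967 genes on the array, 15955 have their Entrez identifier in the reference table, and 0 of these have another symbol there. Genome positions of the probes were not used here.

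The scanner intensities were background-corrected and quantile-normalized with the neqc function of limma 3.58.1 in R 4.3.3, with negative controls inferred from the detection p-values and an offset of 16, and analysed on the log2 scale. Probes with a detection p-value under 0.05 on at least 3 of the 12 arrays were kept, which left 13421. Of these, 11787 named 1 gene, and the probe with the highest mean over all arrays stood for its gene, which left 9657 genes to test; 1721 of them had several detected probes. A limma linear model with a mean for each of the 4 days (8 residual degrees of freedom) was fitted to all 12 arrays, with moderated variances that follow the mean intensity. A gene was called changed at a Benjamini-Hochberg adjusted p-value under 0.05 over all tested genes. A moderated F-test over the 4 days found the genes that changed at any stage, and these were counted by the day of their highest mean.

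Changes are given as log2 differences of day means with the standard error of the fit, for n = 3 arrays per day; day levels are means with the standard deviation of 3 arrays. For a gene whose probe was not detected on any of the 3 arrays of its dimmer day, the fold is a lower bound, taken from the brighter day's mean and the mean detection floor of the arrays of the dimmer day (floors between 5.04 and 5.33 on the log2 scale). Where the probe was detected on 1 or 2 of these arrays, the number is given beside the gene; no fold is given for such a gene when its mean lies under the mean floor of that day. A log2 change printed beside a lower bound is the fitted difference, which includes signal under the floor, and is itself no bound. The number of arrays limits the precision of every value. The fit was tested on simulated data, drawn from each gene's mean on day 0 and its residual spread, for day 4 against day 0. Of the genes moved by 0.5 on the log2 scale 31.3% were called, of those moved by 1 82.1% and of those moved by 2 98.5%, and 2.76% of the calls were false. With the pluripotency list moved by 0.5, that list was called and 0 of the other 22 were. The noise was independent between genes, so this does not show how the list test behaves with correlated genes. Of 9657 genes, 67, 67 and 66 were moved by 0.5, 1 and 2. In the data 27.0% of genes were called for day 4 against day 0, so these shares need not carry over.

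The lists of genes were fixed before the data were examined: pluripotency, primed epiblast, primitive streak, definitive endoderm, pancreatic progenitor, endocrine pancreas, exocrine pancreas and duct, liver, other endoderm organs (gut, lung and thyroid), extraembryonic endoderm, trophoblast, cardiac mesoderm, mesenchyme and smooth muscle, endothelium and blood, neural, epithelium, retinoic acid response, activin and nodal response, FGF response, WNT and BMP response, cell cycle, p53 and cell stress, and hypoxia and glycolysis. Each of these 23 lists was tested against the other genes with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison, and again with the correlation estimated from the arrays. Members were counted as changed after adjustment over all genes and after adjustment over the list alone.

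The genes named in the text follow a rule fixed at the same time. For each comparison it takes the 10 genes with the largest rise and the 10 with the largest fall among called genes whose arrays of the 2 days do not overlap and that are detected on all 3 arrays of the brighter day, passing over unnamed clones. It adds 2 members per list and direction, 5 transcription factor symbols per direction, the Hox genes and a panel of 38 markers. Other choices fixed at the same time and varied one by one were the background correction and normalization, the authors' value table, the filter on dim probes, the mean of all probes of a gene, the 6 arrays of the compared days alone, the variance trend, array weights, the replicate number as a block, a 2-fold minimum change and leaving out each array. Replicates 2 and 3 alone, and all detected probes with the unnamed ones included, were added after seeing the data, and so was a test of each list on its members in no other list. The chip as a block was not run because the files give no chip for any array. No column of per-sample values was left out; probes that were detected but name no gene (1634, or 12.2% of the detected probes) are outside the comparisons of genes.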

Results

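The series follows W9.5 mouse embryonic stem cells from the undifferentiated state (day 0) through days 4, 8 and 15 of a protocol toward pancreatic progenitors, with 3 arrays per day. On average 11602 ± 312 probes (SD, n = 3) were detected on day 0, 11797 ± 512 on day 4, 11950 ± 159 on day 8 and 12401 ± 139 on day 15, with between 11253 and 12554 on single arrays. The difference between day 15 and day 0 was 798.7 probes (exact permutation test, two-sided p = 0.1, the smallest that 3 arrays against 3 allow). The median scanner intensity lay between 71.2 and 86.3 on the 12 arrays.

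The 4 days stood apart from each other. Correlations of log2 levels across genes were between 0.987 and 0.993 for arrays of 1 day and at most 0.968 for arrays of different days (genes are not independent replicates). The first principal component held 70.8% of the variance and placed days 0 and 4 opposite days 8 and 15, and the second held 10.7%. Over the 4 days, 7259 of 9657 genes changed (moderated F-test): 2485 had their highest mean on day 0, 1285 on day 4, 1386 on day 8 and 2103 on day 15.

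**Figure D1:**
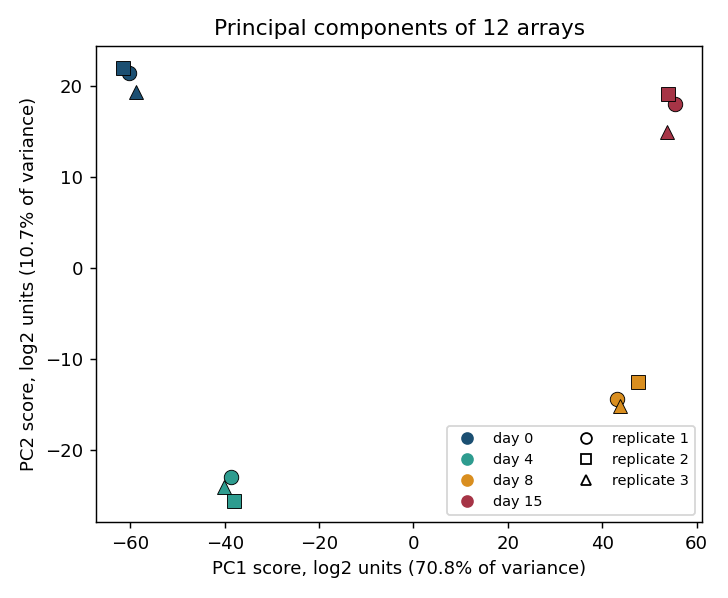
Scores of the 12 arrays on the first and second principal components of the normalized log2 intensities of 9657 genes, in log2 units (70.8% and 10.7% of the variance). Colours mark the day and shapes the replicate number; each day's 3 arrays lie together, and the first component parts days 0 and 4 from days 8 and 15.

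**Figure D2:**
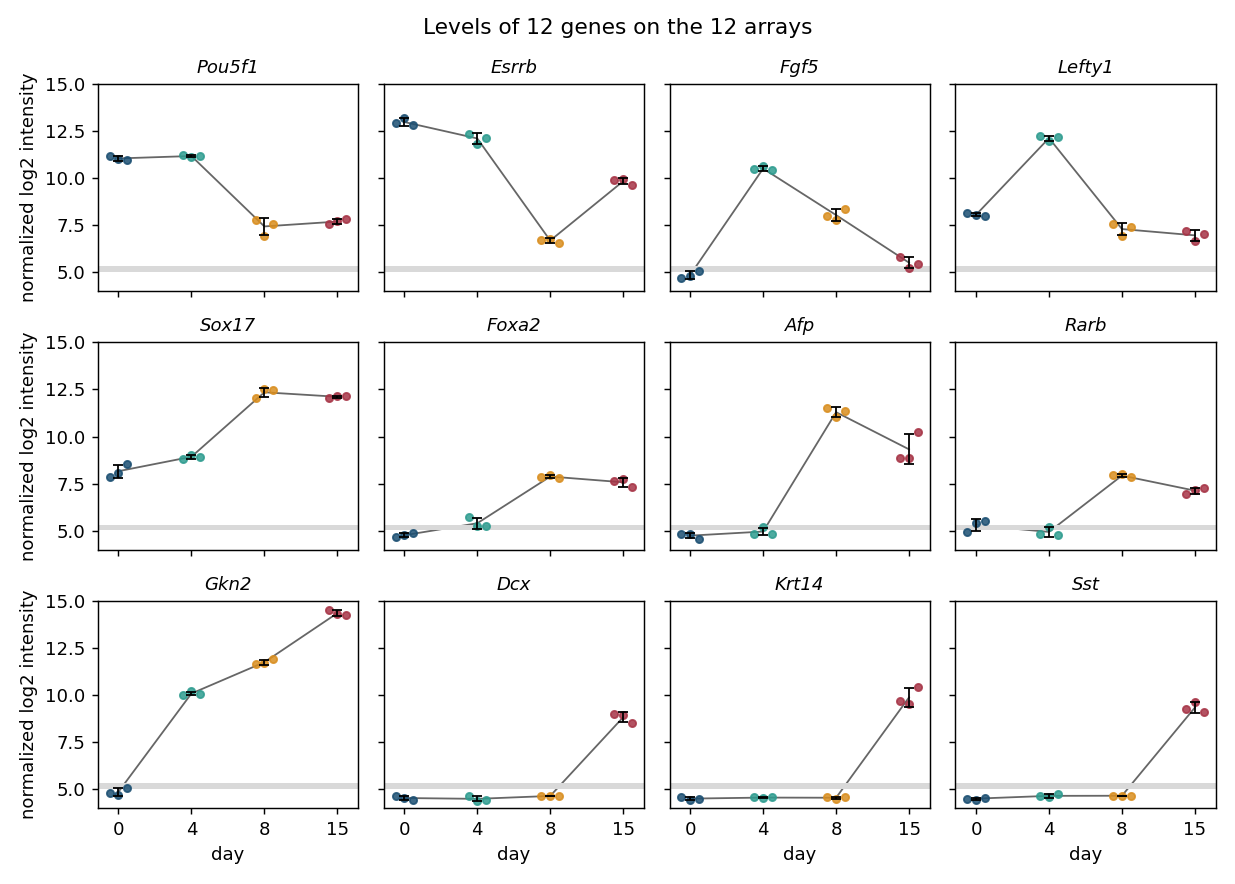
Normalized log2 intensity of 12 genes on the 12 arrays, by day. Points are single arrays, black bars are the mean ± SD of 3 arrays, and the grey band spans the detection floors of the arrays (5.04 to 5.33). Fgf5 and Lefty1 are highest on day 4, Foxa2, Rarb and Afp on day 8, and Gkn2, Dcx, Krt14 and Sst on day 15.

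The comparison of day 4 with day 0 covers the first step, where a step means the interval between successive sampled days. The labels do not tie any step to a single agent. Genes of the primed, post-implantation epiblast rose as a list, and the single genes with the largest rises included inhibitors of nodal and proteins of the stomach lining. Fgf5, a growth factor of the epiblast, was not detected on day 0 and was at least 38.3-fold higher on day 4 (log2 change 5.64 ± 0.19, SE, n = 3 arrays per day, adjusted p = 4.8e-13). Lefty1 and Lefty2, secreted inhibitors of nodal, rose 16.8-fold (4.07 ± 0.17) and 15.4-fold (3.95 ± 0.14). The gastrokines Gkn1 and Gkn2, proteins of the stomach lining, rose 32.1-fold and at least 28.6-fold (5.21 ± 0.13), and Pga5, the precursor of a gastric protease, rose 20.5-fold (4.36 ± 0.10). Ttr, a carrier of thyroid hormone and retinol made by visceral endoderm and liver, was at least 28.5-fold higher (5.48 ± 0.14). Fgf15, an endocrine growth factor, rose 17.2-fold, Clic6, a chloride channel protein, 21.1-fold, and the surface proteins Timd2 and Muc13 at least 14.2-fold and at least 10.4-fold.

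The single genes with the largest falls came from several pathways. Socs3, a feedback inhibitor of cytokine signalling, fell by 4.79 ± 0.18 on the log2 scale (27.6-fold, adjusted p = 2.5e-12), and Stra8, a retinoic acid target of germ cells, was at least 16.5-fold lower. The immediate early genes Fos, Egr1 and Egr4 were 12.5-fold, 5.85-fold and at least 7.44-fold lower. Inhbb, an activin subunit, was 12.7-fold lower, Bmp4, a BMP ligand, 9.89-fold, and Id1, a target of BMP signalling, 8.98-fold. The chemokine Cxcl1 was lower, reaching the detection floor on day 4 (detected on 1 of 3 arrays), the adhesion protein Ceacam1 was 8.84-fold lower, and the hormone Insl3 at least 5.24-fold lower. Klf4, a transcription factor of the naive pluripotent state, fell by 2.52 ± 0.11 (5.72-fold) and Nanog, another, by 0.84 ± 0.19. No change was called for Pou5f1 (0.13 ± 0.17, adjusted p = 0.63), Sox2 (0.06 ± 0.17, adjusted p = 0.84) or Zfp42 (-0.38 ± 0.14, adjusted p = 0.057). For Zfp42 this turned on the choices made: it was called lower with the replicate number as a block (adjusted p = 0.0219), in the authors' table (0.0348), with an offset of 50 (0.0493), with median scaling (0.00544), and without day 0 replicate 3 (0.0462) or day 4 replicate 3 (0.0232). Over all alternatives its adjusted p lay between 0.00544 and 0.231.

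In all, 2611 genes changed from day 0 to day 4 (1420 higher, 1191 lower; 463 higher and 218 lower by at least 2-fold), and 10 of the 23 lists shifted, 8 of them upward. All 7 tested primed epiblast genes, of 9 with a probe on the array, rose, with a mean log2 change of 2.47 (adjusted p = 7.7e-11), Pou3f1 by 8.93-fold and Sall2 by 4.05-fold among them. Lef1, also of this list, was detected on day 4 alone. It entered the test through those arrays, which favours a rise of the list by day 4 and a fall after it. Of 19 measured extraembryonic endoderm genes 13 rose and 6 did not pass the test (mean 0.87, adjusted p = 5.4e-07). Among them were Ttr and the proteoglycan gene Srgn (3.94-fold). Adjusted over the list alone, 13 rose and 1 fell. Definitive endoderm genes rose in 11 of 19 cases and fell in 2 (mean 1.01, adjusted p = 1.3e-06; 13 and 2 adjusted over the list alone), with Tmprss2, a membrane protease, at least 5.20-fold higher. Of 18 mesenchyme and smooth muscle genes 11 rose and 1 fell (mean 0.80, adjusted p = 1.3e-05; 14 and 1 adjusted over the list alone). The matrix genes Dcn and Col3a1 rose 7.75-fold and 3.55-fold. Of 15 p53 and cell stress genes 8 rose (mean 0.72, adjusted p = 5.4e-05). Chac1, which degrades glutathione, rose 11.6-fold and Cdkn1a, a cell cycle inhibitor, 2.69-fold. Hypoxia and glycolysis genes rose in 8 of 15 cases and fell in 1 (mean 0.56, adjusted p = 0.0013). Epithelial genes rose in 10 of 16 cases and fell in 2 (mean 0.68, adjusted p = 0.0015), including Krt18 (4.56-fold) and Cldn7 (at least 3.70-fold). Counts adjusted over the list alone were the same for these 3 lists and for the primed epiblast. Of 25 pluripotency genes 13 fell and 2 rose (mean -0.57, adjusted p = 6.5e-05; 14 and 2 adjusted over the list alone), the DNA demethylase Tet2 by 3.13-fold.

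A further pair of lists shifted only at the preset correlation. Activin and nodal response genes rose in 7 of 9 cases, the same adjusted over the list alone, and Inhbb fell (mean 0.88, adjusted p = 0.0027, but adjusted p = 0.114 with an estimated correlation). FGF response genes fell in 7 of 13 cases and rose in 1 (mean -0.54, adjusted p = 0.0328, but adjusted p = 0.134 with an estimated correlation; 7 and 3 adjusted over the list alone), with Etv4, an ETS factor downstream of FGF, 5.26-fold lower. The FGF list lost its call without day 0 replicate 2 (adjusted p = 0.0598) and without day 4 replicate 2 (adjusted p = 0.0567), with the replicate number as a block (0.0542), with no filter on dim probes (0.0739) and with the strict detection filter (0.078), and its adjusted p lay between 0.0142 and 0.134 over all alternatives. The other 13 lists were not called. Of 11 primitive streak genes 6 rose and 1 fell (adjusted p = 0.0799). Eomes, a T-box factor of the streak, rose 2.64-fold. The pancreatic progenitor list (mean 0.02, adjusted p = 0.847) held Hnf4a, a nuclear receptor of endoderm, which rose 4.58-fold, and Nr5a2, which fell by 1.29 ± 0.15. The other adjusted p-values were 0.99 for endocrine pancreas, 0.895 for exocrine pancreas and duct, 0.189 for liver and for retinoic acid response, 0.916 for other endoderm organs, 0.095 for trophoblast, 0.31 for neural, 0.136 for cell cycle, and 0.399 for cardiac mesoderm, endothelium and blood, and WNT and BMP response. Mean, median and test differed in sign for 4 lists of this comparison, none of them called.

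**Figure D3:**
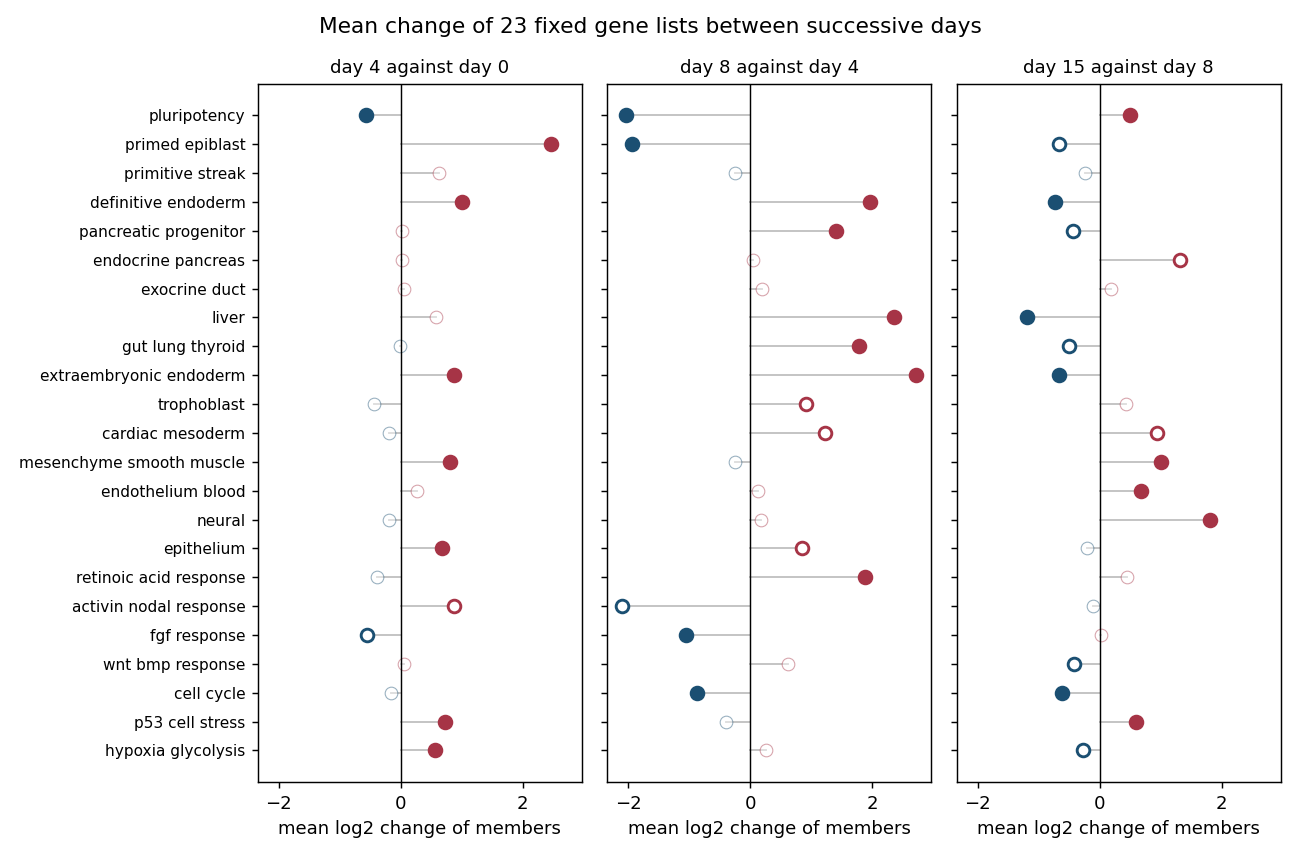
Mean log2 change of the tested members of 23 gene lists, for day 4 against day 0, day 8 against day 4 and day 15 against day 8. Filled circles are lists called also with an estimated correlation, thick open circles are called only with the preset correlation, and thin pale circles are not called; red is above 0 and blue below. Primed epiblast genes are farthest right in the first panel (2.47), extraembryonic endoderm in the second (2.73) and neural genes in the third (1.82).

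The comparison of day 8 with day 4 covers the second step, and it had the most changes of the 3 steps. Genes of endoderm, of liver and of the retinoic acid response rose, and genes of the pluripotent and epiblast states fell. Apoa2, an apolipoprotein of high-density lipoprotein, rose 106-fold (6.73 ± 0.18, adjusted p = 2.2e-14; detected on 2 of 3 arrays on day 4), and Afp, a plasma protein of visceral endoderm and fetal liver, was at least 68.1-fold higher (6.32 ± 0.27). Sox17, a master factor of endoderm, rose 10.7-fold (3.42 ± 0.16), Foxa2, a pioneer factor of endoderm, 5.56-fold (2.48 ± 0.17), and Gata4 and Gata6, zinc finger factors of endoderm, 5.24-fold and 4.66-fold. Rfx6, a factor of gut and pancreatic endoderm, was at least 14.1-fold higher (4.31 ± 0.16), and Sox9, a factor of pancreatic progenitors among other tissues, rose 4.79-fold (2.26 ± 0.16). Rarb, a retinoic acid receptor induced by its ligand, rose from 4.94 ± 0.25 (SD, n = 3, detected on 1 of 3 arrays) on day 4 to 7.93 ± 0.09 on day 8. Cyp26a1, which degrades retinoic acid, rose 5.98-fold. Its rise had begun earlier, from 5.08 on day 0 (detected on 1 of 3 arrays) to 7.06 on day 4. Hoxb1, a member of the retinoic acid list, lay at 5.28 on day 4 and 5.37 on day 8, under its day 0 mean of 6.21.

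Among other large rises, Clps, a cofactor of pancreatic lipase, and Nepn, a proteoglycan gene, were at least 23.9-fold and at least 27.5-fold higher, and Myl3, a cardiac myosin light chain, at least 22.2-fold. The plasma phosphoprotein Spp2 rose 26.0-fold, the ion transport regulator Fxyd3 and the parathyroid hormone receptor Pth1r 25.3-fold each, the VEGF receptor Flt1 23.7-fold and the sulfotransferase Hs3st1 22.2-fold. Irx3, a homeobox factor, was at least 11.8-fold higher. In the other direction, Lefty2 fell by 5.89 ± 0.14 on the log2 scale (59.2-fold, adjusted p = 8.3e-15) and Lefty1 by 4.82 ± 0.17 (28.3-fold). Esrrb, a nuclear receptor of the naive pluripotent state, was 42.5-fold lower, Klf2 27.4-fold, Tdgf1, the nodal co-receptor, 24.8-fold, Zfp42 14.6-fold, Pou5f1 13.3-fold (-3.73 ± 0.17), Sox2 7.31-fold and Nanog 3.36-fold. Tcf15, a bHLH factor of the epiblast, was 21.8-fold lower, the lysosomal protein Laptm5 30.8-fold, the clathrin uncoating factor Dnajc6 27.0-fold, the zinc finger gene Zfp819 23.8-fold, the oxidase Enox1 at least 25.3-fold and the guidance receptor Robo4 at least 17.2-fold. Dnajc6 and Zfp819 were detected on 1 of 3 arrays on day 8.

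In all, 5323 genes changed from day 4 to day 8 (2715 higher, 2608 lower; 1105 higher and 911 lower by at least 2-fold), and 14 lists shifted, 9 upward. Of 19 extraembryonic endoderm genes 18 rose (mean 2.73, adjusted p = 4.0e-14), including Afp and Pth1r. Definitive endoderm genes rose in 15 of 19 cases (mean 1.97, adjusted p = 3.9e-09), the trypsin inhibitor Spink1 by 15.4-fold, while the hormone gene Trh fell by 2.38 ± 0.20. Retinoic acid response genes rose in 13 of 14 cases (mean 1.88, adjusted p = 3.2e-07), Meis1, a homeobox factor, by 8.60-fold. Liver genes rose in 11 of 13 cases (mean 2.36, adjusted p = 1.5e-06). Pancreatic progenitor genes rose in 13 of 15 cases (mean 1.41, adjusted p = 9.9e-06), with Isl1, a LIM factor, 5.82-fold higher (detected on 2 of 3 arrays on day 4), and Nr5a2 fell from 8.22 ± 0.09 (SD, n = 3) on day 4 to the detection floor on day 8 (detected on 2 of 3 arrays). The 15 are the tested members of 22 with a probe on the array, and Pdx1, Ptf1a, Nkx6-1 and Nkx2-2 are not among them. Of these 15 genes 8 are also in another list. Of the other 7, chosen after the values were seen, 6 rose (mean 0.89, unadjusted camera p = 0.0248, but 0.109 with an estimated correlation). Genes of other endoderm organs rose in 6 of 7 cases (mean 1.78, adjusted p = 0.00069), among them Tff3, a trefoil peptide of gut mucus (at least 8.99-fold), and the hedgehog ligand Ihh (9.82-fold, detected on 2 of 3 arrays on day 4). Pluripotency genes fell in 19 of 25 cases and rose in 4 (mean -2.03, adjusted p = 6.7e-08), Klf4 by 6.69-fold among those that rose. Cell cycle genes fell in 19 of 20 cases (mean -0.87, adjusted p = 1.5e-06), cyclin Ccne1 4.30-fold and the topoisomerase Top2a 2.36-fold. Primed epiblast genes fell in 6 of 7 cases (mean -1.94, adjusted p = 4.6e-05), including Otx2 (11.5-fold) and Pou3f1 (8.88-fold). FGF response genes fell in 8 of 13 cases and rose in 1 (mean -1.05, adjusted p = 0.00075), including Etv1 (6.55-fold) and Etv5 (5.85-fold). Adjusted over the list alone, each of these counts was the same.

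Of the lists called only at the preset correlation, epithelial genes rose in 9 of 16 cases and fell in 2 (mean 0.85, adjusted p = 0.0103, but adjusted p = 0.059 with an estimated correlation; 10 and 2 adjusted over the list alone), with Krt8 6.37-fold and Krt19 7.51-fold higher (Krt19 detected on 1 of 3 arrays on day 4). Activin and nodal response genes fell in 6 of 9 cases and rose in 2 (mean -2.10, adjusted p = 0.0021, but adjusted p = 0.0837 with an estimated correlation), Fst, an activin antagonist, by 9.40-fold among those that rose. Marker genes of other lineages moved as well: cardiac mesoderm genes rose in 5 of 10 cases (mean 1.23, adjusted p = 0.041, but adjusted p = 0.241 with an estimated correlation) and trophoblast genes in 5 of 7 (mean 0.92, adjusted p = 0.0446, but adjusted p = 0.0928 with an estimated correlation), with 1 fall in each and the same counts adjusted over the list alone for these 3 lists. Examples are the troponin Tnnc1 (19.2-fold higher), the keratin Krt7 (4.58-fold) and Plac1, a placental gene (at least 2.80-fold). Both calls ended without day 4 replicate 3 (adjusted p = 0.0594 and 0.0559), with the replicate number as a block (0.053 for each) and with the 6 arrays of these days alone (0.0543 and 0.0534). The cardiac call also ended with no filter (0.0854), the strict filter (0.0607) and median scaling (0.0641), and the trophoblast call with the mean of all probes (0.0826). Over all alternatives the adjusted p lay between 0.0241 and 0.241 for the cardiac list and between 0.0327 and 0.0928 for the trophoblast list. The adjusted p-values of the 9 lists without a call were 0.942 for primitive streak, 0.987 for endocrine pancreas, 0.815 for exocrine pancreas and duct, 0.339 for mesenchyme and smooth muscle, 0.114 for WNT and BMP response, 0.65 for endothelium and blood and for neural, and 0.226 for p53 and cell stress and for hypoxia and glycolysis. Mean, median and test differed in sign for 3 lists, none of them called.

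The comparison of day 15 with day 8 covers the last step. Neural and mesenchyme genes rose as lists, and definitive endoderm, liver and cell cycle genes fell as lists. The extraembryonic endoderm list was called lower too, with 7 of 19 members lower and a median log2 change of -0.03. The epithelium and trophoblast lists were not called, though single keratin and placental genes were among the largest rises. Krt14 and Krt15, keratins of basal epithelium, were at least 26.3-fold (5.32 ± 0.19, adjusted p = 2.3e-12) and at least 16.7-fold higher. Sst, the hormone somatostatin of pancreatic delta cells and of other endocrine and neural cells, was at least 18.1-fold higher (4.68 ± 0.15). Dcx, a microtubule protein of young neurons, and Prl2a1, a placental prolactin gene, were at least 12.7-fold and at least 13.5-fold higher. Amn, an uptake receptor subunit of visceral endoderm, fell by 5.33 ± 0.15 on the log2 scale (40.2-fold, adjusted p = 1.9e-13), Apoa2 by 4.03 ± 0.18 (16.3-fold), and the lipoprotein genes Apom, Apob and Mttp 17.8-fold, 9.83-fold and 8.63-fold (Apob detected on 2 of 3 arrays on day 15).

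Other large rises were those of Nupr1, a stress-induced regulator (24.2-fold), the placental cathepsin Ctsj (14.7-fold, detected on 2 of 3 arrays on day 8), the muscle actin Acta1 (13.2-fold), Wfdc1 (11.9-fold) and Rufy3, a neuronal adaptor (11.9-fold, detected on 2 of 3 arrays on day 8). Transcription factor genes with large rises were Esrrb (8.84-fold), Nr2f1 (7.45-fold), Gbx2 (6.56-fold), Klf2 (6.07-fold) and Zeb1 (5.15-fold). Tfec, a bHLH factor, was 14.1-fold lower (detected on 2 of 3 arrays on day 15), the lectin Lgals2 10.6-fold, complement C2 9.70-fold, Spp2 9.58-fold and the peptidase Dpp4 9.41-fold. Among transcription factors Rfx6 fell 6.52-fold (-2.70 ± 0.16), Hhex, a homeobox factor of liver and pancreas development, 4.38-fold (-2.13 ± 0.16), Id1 4.25-fold, Cited1 3.27-fold and Eomes 3.08-fold. Sox17 (-0.24 ± 0.16, adjusted p = 0.32), Foxa2 (-0.30 ± 0.17, adjusted p = 0.24) and Sox9 (0.11 ± 0.16, adjusted p = 0.69) had no called change.

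In all, 2123 genes changed from day 8 to day 15 (1216 higher, 907 lower; 396 higher and 184 lower by at least 2-fold), and 16 lists shifted, 7 upward. Neural genes rose in 12 of 15 cases (mean 1.82, adjusted p = 8.7e-15), with the neurofilament gene Nefm at least 8.77-fold higher. The 15 are the tested members of 24 with a probe on the array. Dcx and Nefm were detected on day 15 alone and entered the test through the arrays where they are high, which favours a rise of the list. Mesenchyme and smooth muscle genes rose in 11 of 18 cases (mean 1.00, adjusted p = 8.3e-08), including Col3a1 (6.23-fold) and the matrix gene Lum (at least 5.93-fold). Pluripotency genes rose in 10 of 25 cases and fell in 3 (mean 0.50, adjusted p = 8.6e-05; 14 and 3 adjusted over the list alone): Esrrb, Klf2 and Zfp42 (2.62-fold) rose, Tbx3 and Lin28a fell by 1.61 ± 0.13 and 1.51 ± 0.19, and Pou5f1 had no called change (0.26 ± 0.17, adjusted p = 0.33). Endothelium and blood genes rose in 6 of 12 cases and fell in 2 (mean 0.68, adjusted p = 0.0015), with Esam and Cdh5, endothelial adhesion genes, 4.83-fold and 4.26-fold higher. Of 15 p53 and cell stress genes 6 rose and 1 fell (mean 0.60, adjusted p = 0.0049), Chac1 by 6.57-fold and Trib3 by 5.65-fold. Cell cycle genes fell in 14 of 20 cases (mean -0.62, adjusted p = 3.5e-09; 19 adjusted over the list alone), Rrm2, a subunit of ribonucleotide reductase, by 1.98-fold. Definitive endoderm genes fell in 9 of 19 cases and rose in 2 (mean -0.73, adjusted p = 1.6e-06; 12 and 2 adjusted over the list alone), Spink1 by 6.91-fold. Liver genes fell in 8 of 13 cases, while Dlk1, a hepatoblast surface gene, rose 2.98-fold (mean -1.20, adjusted p = 4.9e-06). Extraembryonic endoderm genes fell in 7 of 19 cases, Apoe, an apolipoprotein, by 6.97-fold, while Thbd rose 3.44-fold (mean -0.66, adjusted p = 0.0045). The median of this list was -0.03 and 11 members had no call, so a minority with large falls carried the mean. On its 14 members in no other list the unadjusted camera p was 0.0391, but 0.0596 with an estimated correlation. For the lists of this paragraph with no second count, adjusting over the list alone gave the same numbers.

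Calls at the preset correlation only were made for 7 lists. Endocrine pancreas genes rose in 6 of 9 cases and fell in 1 (mean 1.31, adjusted p = 8.6e-05, but adjusted p = 0.0519 with an estimated correlation), with Sst and Myt1, a zinc finger factor of endocrine and neural precursors (at least 4.94-fold), the largest rises and Isl1 lower. The 9 are the tested members of 24 with a probe on the array. Sst and Myt1 were detected on day 15 alone and entered the test through the arrays where they are high, which favours a rise of the list. Cardiac mesoderm genes rose in 7 of 10 cases and fell in 2 (mean 0.95, adjusted p = 0.0002, but adjusted p = 0.0645 with an estimated correlation), the troponin Tnnt2 at least 4.53-fold. The 10 are the tested members of 18 with a probe on the array, and Tnnt2 too was detected on day 15 alone. Primed epiblast genes fell in 3 of 7 cases and rose in 1 (mean -0.67, adjusted p = 0.016, but adjusted p = 0.124 with an estimated correlation), Fgf5 by 5.75-fold. Pancreatic progenitor genes fell in 5 of 15 cases and rose in 2 (mean -0.44, adjusted p = 0.0292, but adjusted p = 0.0645 with an estimated correlation; 6 and 3 adjusted over the list alone), and the 7 members in no other list had a mean of -0.05 (unadjusted p = 0.729). Genes of other endoderm organs fell in 4 of 7 cases and rose in 1 (mean -0.51, adjusted p = 0.0387, but adjusted p = 0.0789 with an estimated correlation). Hypoxia and glycolysis genes fell in 7 of 15 cases and rose in 1 (mean -0.27, adjusted p = 0.0387, but adjusted p = 0.0777 with an estimated correlation). WNT and BMP response genes fell in 5 of 10 cases and rose in 2 (mean -0.42, adjusted p = 0.0466, but adjusted p = 0.0858 with an estimated correlation). Examples are the microvillus gene Vil1 (2.33-fold lower), the glucose transporter Slc2a3 (2.59-fold lower) and Id2 (2.51-fold lower); except for the pancreatic progenitor list, counts adjusted over the list alone were the same. These last 3 lists lost their call when 1 array was left out: other endoderm organs without day 15 replicate 1 (adjusted p = 0.0624, range over all alternatives 0.0206 to 0.375), hypoxia and glycolysis without day 8 replicate 1 (0.0622, range 0.0128 to 0.0877), and WNT and BMP response without day 8 replicate 1 (0.0598) or day 15 replicate 1 (0.0624, range 0.0383 to 0.0858). The WNT and BMP call also ended under all 4 other normalizations and with the replicate number as a block (0.0604), among other choices. The call of the other endoderm organs ended with no filter (0.375), median scaling (0.0704) and replicates 2 and 3 alone (0.0617), and the hypoxia call with the strict filter (0.0877), no variance trend (0.0527) and replicates 2 and 3 alone (0.0611). The adjusted p-values of the lists with no call were 0.778 for primitive streak, 0.37 for exocrine pancreas and duct, 0.231 for trophoblast, 0.174 for epithelium, 0.113 for retinoic acid response, 0.79 for activin and nodal response and 1 for FGF response. Crabp1, a retinoic acid binding protein, rose 8.54-fold and Prl2c2, a placental prolactin gene, 8.37-fold, the largest rises in the retinoic acid and trophoblast lists. Mean, median and test differed in sign for 3 lists, none of them called.

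The comparison of day 15 with day 0 sets the end of the protocol against its start. Gkn2 was at least 548-fold higher (9.47 ± 0.13, adjusted p = 1.0e-18), Gkn1 421-fold (8.72 ± 0.14) and Pga5 92.8-fold. Igfbp5, an IGF binding protein, rose 186-fold (detected on 1 of 3 arrays on day 0), Ttr at least 110-fold, Myl3 at least 92.1-fold, Gdf9, a TGF-beta family growth factor of oocytes, at least 68.5-fold, Fxyd3 64.2-fold (detected on 2 of 3 arrays on day 0) and Wfdc1 at least 42.3-fold. Flt1 rose from 5.12 on day 0, under the mean detection floor of that day and detected on 1 of 3 arrays, to 11.8 on day 15. Transcription factor genes with the largest rises were Nr2f1 (30.3-fold), Irf2 (at least 17.3-fold), Sox17 (15.4-fold, 3.94 ± 0.16), Zic1 (at least 11.2-fold) and Irx3 (at least 10.7-fold). Tcf15 fell by 5.10 ± 0.15 on the log2 scale (34.3-fold), Laptm5 by 4.94 ± 0.18 (30.6-fold) and Etv4 by 4.30 ± 0.18 (19.7-fold), and Eras, a Ras protein of embryonic stem cells, was 17.6-fold lower. The carbonyl reductase Cbr3 was 20.8-fold lower, Robo4 17.3-fold, Tdgf1 15.8-fold, Inhbb 15.3-fold, Dppa2 and Utf1, chromatin proteins of pluripotent cells, 14.9-fold and 14.4-fold, and Pou5f1 10.2-fold (-3.35 ± 0.17).

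In all, 6523 genes differed between day 15 and day 0 (3083 higher, 3440 lower), and 15 lists shifted, 11 upward. Among changes of at least 2-fold the balance turned, with 1652 higher and 1392 lower. The median change of all genes was -0.11, and under the 4 other normalizations it lay between -0.10 and -0.07. All 20 cell cycle genes fell (mean -1.66, adjusted p = 8.8e-09), and pluripotency genes fell in 22 of 25 cases and rose in 3 (mean -2.10, adjusted p = 8.8e-09). FGF response genes fell in 11 of 13 cases (mean -1.58, adjusted p = 0.00014), among them Spry4, a feedback inhibitor of FGF signalling (9.66-fold). Extraembryonic endoderm genes rose in 17 of 19 cases and fell in 2 (mean 2.93, adjusted p = 2.8e-09), Thbd by 28.7-fold, while Amn fell by 3.67 ± 0.15. Definitive endoderm genes rose in 16 of 19 cases and fell in 3 (mean 2.25, adjusted p = 1.3e-06), and retinoic acid response genes rose in 12 of 14 and fell in 2 (mean 1.95, adjusted p = 8.3e-05). Of the 15 pancreatic progenitor genes tested, among 22 with a probe, 11 rose and 2 fell (mean 0.98, adjusted p = 0.0057). The unadjusted camera p was 0.192 for the 7 members in no other list. Foxa2 was at least 5.04-fold and Gata4 5.41-fold higher, and Nr5a2 was 7.39-fold lower. Mesenchyme and smooth muscle genes rose in 14 of 18 cases and fell in 1 (mean 1.56, adjusted p = 0.00011), Col3a1 by 21.9-fold. Of the 15 neural genes tested, among 24 with a probe, 12 rose and 1 fell (mean 1.80, adjusted p = 0.00014, and 0.0495 with an estimated correlation). Gap43, a growth cone gene, rose 15.4-fold.

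The remaining calls of this comparison were lost with an estimated correlation. Of the 10 cardiac mesoderm genes tested, among 18 with a probe, 9 rose (mean 1.98, adjusted p = 0.00034, but adjusted p = 0.0766 with an estimated correlation). Epithelial genes rose in 10 of 16 cases and fell in 3 (mean 1.32, adjusted p = 0.0106, but adjusted p = 0.0629 with an estimated correlation), Krt7 by 18.5-fold. Liver genes rose in 7 of 13 cases and fell in 1 (mean 1.74, adjusted p = 0.0125, but adjusted p = 0.166 with an estimated correlation). Of the 9 endocrine pancreas genes tested, among 24 with a probe, 6 rose and 1 fell (mean 1.38, adjusted p = 0.017, but adjusted p = 0.166 with an estimated correlation). Genes of other endoderm organs rose in 5 of 7 cases (mean 1.26, adjusted p = 0.0286, but adjusted p = 0.0799 with an estimated correlation). Activin and nodal response genes fell in 6 of 9 cases and rose in 1 (mean -1.33, adjusted p = 0.023, but adjusted p = 0.166 with an estimated correlation). For all 15 called lists, adjusting over the list alone gave the same counts. The endocrine pancreas and other endoderm organ lists lost their calls with no filter on dim probes (adjusted p = 0.207, range over all alternatives 0.00719 to 0.207, and 0.131, range 0.019 to 0.131). Lists with no call had adjusted p-values of 0.955 for primed epiblast and for exocrine pancreas and duct, 0.603 for primitive streak, 0.151 for trophoblast, 0.138 for endothelium and blood, 0.407 for WNT and BMP response, 0.0661 for p53 and cell stress and 0.229 for hypoxia and glycolysis. Mean, median and test differed in sign for 2 lists, none of them called.

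The panel of 38 markers gives the levels of genes that define the stages of pancreas development. Pdx1, the homeobox factor of the pancreatic bud, was detected on 1 array, on day 8 (day mean 4.98 ± 0.35, SD, n = 3), and its mean was 4.62 ± 0.06 on day 15. Ptf1a, Nkx6-1, Nkx2-2 and Neurog3, further transcription factors of pancreas and endocrine precursors, the acinar enzyme gene Cpa1, the hepatocyte gene Alb, and the early endoderm genes Mixl1 and Cer1 were detected on no array. Gcg, the glucagon gene, was detected on 1 array, on day 4. Ins2, an insulin gene, lay at 5.34 ± 0.22 on day 0 and 5.20 ± 0.07 on day 15, close to the detection floors, with no called change at any step (adjusted p of the F-test 0.872). Sst was detected only on day 15, at 9.34 ± 0.27, and so was Amy2a5, a pancreatic amylase gene, at 5.65 ± 0.11 (at least 1.41-fold above day 8). Neurod1, a bHLH factor of endocrine and neural cells, rose 2.17-fold by day 4, fell by 2.13 ± 0.19 by day 8 and rose 2.10-fold by day 15, ending at 6.57 ± 0.15. Hnf4a rose from 6.29 ± 0.42 on day 0 to 9.95 ± 0.12 on day 8 and fell to 8.70 ± 0.24 on day 15. Onecut1 lay between 4.91 and 5.42 on all days; it was detected on 1 of 3 arrays on day 4 and on 3 on day 8, a rise that was called (adjusted p = 0.013) but not without day 4 replicate 1 (0.0602) or day 8 replicate 2 (0.067, range over all alternatives 0.00842 to 0.0937).

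Of the remaining panel genes, Cxcr4, a chemokine receptor of definitive endoderm, rose from day 8 to day 15 (2.70-fold, 1.44 ± 0.20) and had no called change before. Foxa2 was not detected on day 0; by day 4 it was at least 1.12-fold higher, which was called (adjusted p = 0.0097) but not without day 4 replicate 1 (adjusted p = 0.0607, range over all alternatives 0.00506 to 0.173). Nanog lay at 10.29 ± 0.23 on day 8 and 11.04 ± 0.36 on day 15, a change of 0.75 ± 0.19 that was called (adjusted p = 0.0092) but not without day 8 replicate 2 (adjusted p = 0.0554) or day 15 replicate 3 (0.0526, range over all alternatives 0.000201 to 0.0554). Goosecoid, Gsc, a homeobox gene of the anterior streak, lay between 5.12 and 5.95 on all days, and its calls at single steps did not hold in several of the alternatives. Afp fell by 1.97 ± 0.27 from day 8 to day 15, Ttr by 1.89 ± 0.14 and Rarb by 0.80 ± 0.18. Spry4 was lower at each of the first 2 steps (-0.77 ± 0.18 and -2.41 ± 0.18) and had no called change at the last (-0.10 ± 0.18, adjusted p = 0.76). T and Ins1 have no probe with their name among those used.

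Hox genes, which set position along the body axis, and transcription factor genes as a class were counted as groups. Of 17 Hox genes tested, 6 rose from day 4 to day 8, among them Hoxc9 (4.36-fold), Hoxb2 (3.20-fold), Hoxa5 (at least 2.46-fold) and Hoxb4 (2.46-fold), and Hoxb5 rose 3.65-fold from day 8 to day 15. By day 15, 7 Hox genes were higher than on day 0 and 2 were lower, with Hoxb2 8.33-fold higher (detected on 2 of 3 arrays on day 0). The share of Hox genes that changed, against that of other genes, was 29.4% against 27.0% from day 0 to day 4 (Fisher's exact test, two-sided p = 0.789) and 35.3% against 55.2% from day 4 to day 8 (p = 0.141, exact). It was 29.4% against 22.0% from day 8 to day 15 (p = 0.556, exact) and 52.9% against 67.6% from day 0 to day 15 (p = 0.203, exact). Of 273 transcription factor symbols tested, 38.1% changed from day 8 to day 15 against 21.5% of the other genes (68 higher and 36 lower, Fisher's exact test, two-sided p = 1.08e-09, odds ratio 2.24). The shares were 33.3% against 26.9% from day 0 to day 4 (p = 0.0188 by the same exact test), 60.4% against 55.0% from day 4 to day 8 (p = 0.0738, exact) and 69.2% against 67.5% from day 0 to day 15 (p = 0.6, exact). Genes are not independent, these are 4 tests of 1 family, and the differences between steps were not tested.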

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

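The tests of a share of undifferentiated cells and of the difference between extraembryonic and definitive endoderm were chosen only after the result was seen. Signal was present on probes that the comparisons of genes did not use, those for which the platform annotation lists no gene. Of 1634 such probes detected, 427 were higher and 581 lower on day 15 than on day 0, or 61.7% called, against 65.6% of the detected probes that name 1 gene. No explanation of this was tested.

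Pluripotency genes fell by day 8 and then rose as a list by day 15 (mean log2 change 0.50). The test of more undifferentiated cells of the day 0 kind assumed that all other cells kept their day 8 levels. In that case 1 share of day 0 signal, added to the day 8 signal, would give the day 15 level of all members that had fallen at least 4-fold. At the best share (6.96%), 7 of 16 members lay more than 3 standard errors off, with Sox2, Klf2 and Esrrb above and Pou5f1, Dppa2, Utf1 and Tdgf1 below. With cells of the day 4 kind 8 of 14 lay off. These standard errors are those of the change from day 8 to day 15 alone. The values go against such a share as the only change. Since 2123 genes changed between these days, they do not decide whether undifferentiated cells increased while other cells changed too. The smallest mean change under 4 other normalizations was 0.38, so the rise did not hinge on the choice among them. All 4 bring the arrays to a similar level, so they cannot exclude an effect of scaling itself. Cells in an altered state that express part of the pluripotency genes may explain the rise, as a hypothesis that these arrays of whole cultures do not resolve.

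Extraembryonic endoderm genes rose from day 4 to day 8 with a mean of 2.73. Genes shared with other lists did not account for it: the 14 members in no other list rose by 2.41 on average (camera p = 8.85e-12, and 8.7e-05 with an estimated correlation), 13 of them called. The smallest mean under 4 other normalizations was 2.36, so the rise did not hinge on the choice among them. Each of the 4 brings the arrays to a similar level, so an effect of scaling itself was not tested. Whether extraembryonic endoderm rose more than definitive endoderm cannot be told apart from an equal rise of both: the difference between members in only 1 of the lists was 0.36 (14 against 8 genes, permutation test over genes, two-sided p = 0.628), a test that decides neither way. A mixture of both kinds of endoderm, and cells of 1 kind that express genes of both lists, may each explain the rise.

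Splits of 6 arrays into 3 and 3 number 10, too few for a share under 0.05. In each of the 4 comparisons 1 of the 10 splits, the real one, gave as many genes in limma: 2611, 5323, 2123 and 6523 genes, with 0 in the highest of the other splits. For the change over all 4 days, 1 of 100 splits of the 12 arrays, the real one, gave as many genes (7259, highest other 4751). That is the smallest share these splits allow, and it makes a random grouping of the arrays an unlikely source of the count. It does not tell whether the replicates were separate cultures.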

How the results depend on the processing

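Replicates 2 and 3 alone, all detected probes with unnamed ones, and lists without shared genes were tested only after the results were seen. Calls under the 4 other normalizations numbered 2656 to 2705 from day 0 to day 4, 5225 to 5325 from day 4 to day 8, 2095 to 2113 from day 8 to day 15 and 6324 to 6513 from day 0 to day 15. Replicates 2 and 3 alone gave 2029, 4812, 1493 and 5900, by fewer arrays; the genes lower from day 8 to day 15 numbered 595 (907 with all arrays). Of all detected probes with unnamed ones, 3326, 6962, 2571 and 8736 were called. Leaving out 1 array gave 2082 to 2345, 4779 to 4994, 1697 to 1894 and 6073 to 6220. With a minimum change of 2-fold the counts were 681, 2016, 580 and 3044, and 4051 over the 4 days, by the construction of that choice. With an estimated correlation 9 lists were called from day 8 to day 15 (of 16) and 9 from day 0 to day 15 (of 15); the cause was not tested beyond that choice. Muc1, which fell by 0.45 on the log2 scale from day 8 to day 15, reversed under the mean of all detected probes (0.043, adjusted p = 0.865); its probes were called in opposite directions. The next counts cover all alternatives except leaving out 1 array, with replicates 2 and 3 alone included. Of the values of named genes, 6404 kept direction and side of the threshold, 142 fell short of it, 32 passed it, 24 moved and 1 reversed. For lists, 668 kept both and 47 fell short. When 1 array was left out, 2689 values of named genes kept both, 102 fell short, 11 passed and 48 moved. For lists, 322 then kept both and 8 fell short. Signal over background limits genes near the detection floor, such as Ins2 and Onecut1. The chip as a block was not run, because the files give no chip.

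With the replicate number as a block, 3505, 5894, 2858 and 7035 genes were called, and 9, 12, 15 and 15 lists. The block ended the calls of 4 lists: FGF response at day 4, cardiac mesoderm and trophoblast from day 4 to day 8, and WNT and BMP response from day 8 to day 15. Of 18 pairs with the same number on different days, 14 had correlated deviations above 0.1 (range -0.06 to 0.50), and 10 of 12 arrays had their best partner under their own number. Among days 0, 8 and 15 every such pair lay between 0.31 and 0.50. The pairs under 0.1 all held replicate 2 or 3 of day 4. Replicate 1 of day 4 correlated at 0.47, 0.35 and 0.44 with replicate 1 of days 0, 8 and 15. Replicate 2 of day 4 correlated at 0.24, 0.20 and 0.35 with replicate 3 of days 0, 8 and 15. Replicate 3 of day 4 correlated at 0.28, -0.02 and 0.19 with replicate 2 of those days. The numbers thus mark a shared deviation on days 0, 8 and 15, and for replicate 1 on day 4 too, which the main fit leaves out. They do not pair replicates 2 and 3 of day 4 throughout. The source of the deviation was not tested. The block took the numbers as labelled, so its results for comparisons with day 4 rest on this doubtful pairing.

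Some called lists lean on genes they share with other lists. On members in no other list, the unadjusted camera p was 0.245 for trophoblast, 0.0708 for cardiac mesoderm and 0.25 for epithelium from day 4 to day 8, and 0.729 for pancreatic progenitor and 0.054 for other endoderm organs from day 8 to day 15. From day 0 to day 15 it was 0.192 for pancreatic progenitor, 0.301 for liver and 0.135 for epithelium. Activin and nodal response has 2 such members, too few to test. Definitive endoderm shares 11 of 19 members, and on the other 8 the p from day 4 to day 8 was 6.5e-05.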

Other observations

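After the values were seen, 12 families of genes were put together, several of them around genes already among the largest changes. A test of such a family on the same arrays restates the choice, so only counts of called members and mean log2 changes are given. The sign of these means held in 18 of 18 settings, except that it was not checked for LIF and STAT3 targets, keratins and collagens by day 8, coagulation genes by day 4, and ribosomal genes by day 4 and by day 15. The placental family was prompted by Prl2a1, Prl2c2 and Ctsj: from day 8 to day 15, 10 of 11 members were called higher (mean 2.39), 6 of 7 prolactins and 4 of 4 others, while the trophoblast list fixed beforehand was not called (adjusted p = 0.231). The stomach family was prompted by Gkn1, Gkn2 and Pga5: 4 of 7 members were higher on day 4 than on day 0 (mean 2.42), 4 rose and 1 fell by day 8 (mean 0.66) and 4 rose by day 15 (mean 1.17). Of 11 keratins, 6 rose by day 4 (mean 0.46), 5 rose and 2 fell by day 8 (mean 0.94), and 5 rose by day 15 (mean 1.41), Krt17 by 2.52 on the log2 scale.

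Of 14 targets of the LIF and STAT3 pathway 11 fell by day 4 (mean -1.73), 6 rose and 3 fell by day 8 (mean 0.57) and 7 rose by day 15 (mean 0.66); Socs3 fell by 4.79 on the log2 scale and then rose by 4.28. Of 22 genes of the response to amino acid shortage 15 rose and 1 fell by day 4 (mean 1.23), 2 rose and 17 fell by day 8 (mean -1.18) and 14 rose by day 15 (mean 1.09). Of 16 genes of cholesterol synthesis 1 rose and 13 fell by day 4 (mean -1.01), 11 rose by day 8 (mean 0.76) and 8 fell by day 15 (mean -0.54). Of 25 interferon response genes 16 rose and 1 fell by day 4 (mean 0.89), 6 rose and 14 fell by day 8 (mean -0.61), and 9 rose and 1 fell by day 15 (mean 0.43). Of 17 germline genes 3 rose and 8 fell by day 4 (mean -0.53), 2 rose and 13 fell by day 8 (mean -1.51) and 9 rose by day 15 (mean 0.66). Of 14 apolipoproteins 6 rose and 1 fell by day 4 (mean 0.44), 9 rose and 1 fell by day 8 (mean 1.68), and 1 rose and 9 fell by day 15 (mean -1.68). Of 20 coagulation and complement genes 4 rose by day 4 (mean 0.34), 12 rose and 2 fell by day 8 (mean 1.14), and 3 rose and 6 fell by day 15 (mean -0.61). Of 23 collagens 10 rose by day 4 (mean 0.51), 7 rose and 5 fell by day 8 (mean 0.04), and 8 rose and 3 fell by day 15 (mean 0.41). Of 48 ribosomal protein genes 4 fell by day 4 (mean 0.0022), 31 fell by day 8 (mean -0.52), and 3 rose and 1 fell by day 15 (mean 0.04).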
